A study of Nothobranchius furzeri with 12 samples.

How the data were processed

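Retina with attached retinal pigment epithelium (RPE) was sequenced from 12 male turquoise killifish, 3 at each of 4 ages (1.5 months, then 3.0, then 4.5, then 6.0). Per the labels, the fish came from a mutant line crossed back over several generations to the short-lived GRZ strain, and the labels used here name neither the mutated gene nor whether each fish carried the mutation, so the genotype could differ between ages. The fish were untreated. Cornea, lens, iris, sclera and choroid were dissected away, and RNA went into Nextera XT libraries read from both ends on a single NovaSeq S4 lane. Library names of replicates 2 and 3 at 4.5 months carry the word "Resub", which the labels do not explain. The time of day of collection and the meaning of the replicate number were not given in the sources used here, and neither were the aligner, the counting program, the annotation and the genome build, so no coordinates are printed.

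The deposited table of counts holds whole numbers of reads per gene with no normalization, for 25122 genes and 12 libraries. Among its values from 1 to 20, 73.16% were even, so both mates of a read couple appear to have been counted and counting error is larger than the totals alone imply. A second deposited table of counts was byte for byte the same and was not used. The authors also gave a normalized table of signal values for 23692 genes, of which 23678 were shared with the count table and 14 names had turned into dates. For 100% of the shared genes, within 0.001, each signal value of the authors was the count plus 1 divided by a size factor per library (0.7736 to 1.189). This table served only to check the counts.

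Gene names were used as deposited. Of the 14589 entries named by a locus number, 5257 took a symbol from the reference table of the NfurGRZ-RIMD1 annotation through the same gene number. That annotation may not be the one the authors counted with. After this, 14824 tested genes had a name and 5893 had none, and 150 symbols were shared by more than 1 tested entry. Paralogs such as rom1 and rom1a, opn1sw and opn1sw2, and csf1r and csf1ra keep their separate values, but the rule for reads shared between paralogs was not given.

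Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the age groups (minimum count 10, minimum total 15), which left 20717 genes and 99.98% of counts; 751 genes had no count in any library. TMM factors, estimateDisp, glmQLFit with robust settings and glmQLFTest gave quasi-likelihood F-tests. A single fit of all 12 libraries by age served the test of any difference among the 4 ages and the 6 contrasts of 2 ages; a second fit gave the slope per month of age. The common biological coefficient of variation was 0.306, with 8 residual degrees of freedom and a median of 3.84 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 changes were the change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 fish. Groups of 3 against 3 have no exact permutation p under 0.1, so the gene tests rest on the spread shared across genes and ages.

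Camera from limma 3.58.1 tested 43 of 44 gene lists against all other genes with a preset correlation of 0.01, adjusted over the lists; a list needed 3 tested members, which the mitochondrially encoded list did not reach. Camera was also run with a correlation estimated per list. The lists covered retinal cells (rod photoreceptors, cone photoreceptors, photoreceptor outer segment and cilium, bipolar, amacrine, horizontal and retinal ganglion cells, Mueller glia, oligodendrocytes and myelin, RPE and visual cycle, melanin synthesis and pigment cells, retinal progenitors and ciliary margin). Immune and vascular lists were microglia and macrophages, T and B lymphocytes, neutrophils and granulocytes, erythrocytes, complement, antigen presentation, interferon response, NF-kB and inflammatory cytokines, endothelium, and mural cells and fibroblasts. Lists for neighbouring tissue were lens, cornea and surface epithelium, and skeletal muscle. Process lists were glial stress response, cell cycle and DNA replication, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, heat shock and chaperones, endoplasmic reticulum stress, antioxidant enzymes, DNA damage and senescence, extracellular matrix, cholesterol synthesis and uptake, glycolysis, synaptic vesicle and transmission, lysosome and autophagy, circadian clock, immediate early genes, human macular degeneration genes, and crystallin chaperones. Some genes sit in several lists, and many markers of immune, vascular and epithelial cells are also expressed by other cells of the eye.

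Sample grouping, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took, for 6.0 against 1.5 months, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap in CPM and whose mean was at least 5 CPM, and 5 in each direction for every other comparison (with no overlap condition for the trend). Unnamed genes were passed over: 7 rises and 2 falls for 6.0 against 1.5 months, 7 and 1 for the trend, 2 and 0 for 3.0 against 1.5 months, 1 and 5 for 4.5 against 3.0 months, 4 and 0 for 6.0 against 4.5 months, and 1 and 2 for 4.5 against 1.5 months. From each list with a camera call or a gene past the threshold, up to 4 members with the smallest adjusted p could be named, and rho, rpe65, gfap, glul, vim, mpeg1, c1qa, c3, cfh, cdkn1a and pcna were always looked up. Genes named outside the rule are said to be so.

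Separation of the ages was tested with an exact permutation test of the pseudo-F of distances on log2 CPM (prior count 2, 500 most variable genes) over all 15400 splits. Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter and a stricter filter (at least 10 counts in 6 libraries), each library left out, replicates 2 and 3 of 4.5 months left out, the replicate number as a further term, fits of only the 2 ages compared, a test against a fold of 1.5 and, for the separation, other gene numbers and a prior count of 0.5. After the data were seen, 3 more were added: leaving out the 3 libraries with the most lens RNA, lens and epithelium list means as covariates, and the ribosomal list mean as a covariate. The pipeline was tested on simulated data with 100 changed genes per fold: at 2-fold it recovered 22 for any difference among the ages and 40 to 53 otherwise, at 4-fold 82 to 91, and 2.86% to 7.04% of calls were false. The simulated counts varied independently between genes and held no structure shared by libraries, such as RNA of neighbouring tissue. These shares therefore need not hold for the real libraries.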

Results

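RNA of retina with attached RPE was measured in 12 male killifish, 3 fish at 1.5 months of age and 3 each at 3.0, at 4.5 and at 6.0 months, to ask how the tissue changes over the life of this short-lived fish. Total counts per library ran from 34.44 M (3.0 months replicate 1) to 50.27 M (1.5 months replicate 3). Means ± SD were 46.98 ± 3.155, 38.59 ± 3.606, 48.96 ± 1.716 and 44.85 ± 3.214 M counts at the 4 ages (n = 3 each). Libraries of the same age correlated at Spearman 0.9628 to 0.9939 (median 0.9774) and libraries of different ages at 0.9539 to 0.9909 (median 0.9749). Both ends of the range within an age came from 4.5 months, replicates 1 and 3 at 0.9628 and the Resub libraries (replicates 2 and 3) at 0.9939. No library was a copy of another, as the lowest chi-square per gene between libraries was 15.06. Principal components 1 and 2 of the libraries held 37.31% and 31.6% of the variance. Component 1 was highest in 6.0 months replicate 1, 4.5 months replicate 1 and 1.5 months replicate 2 (61.54, 45.88 and 31.15). Component 2 was highest in 1.5 months replicate 1 (56.2). These libraries carried RNA of neighbouring tissue, as given below. The ages were not separated over the 500 most variable genes (exact permutation p = 0.4897, pseudo-F 0.9803, 26.88% of the variance between ages), and over all tested genes the exact permutation p was 0.03851 (pseudo-F 1.455). Without the 3 libraries highest on component 1, the exact permutation p over the 500 most variable genes was 0.1571.

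Some libraries carried RNA of neighbouring tissue, as the summed level of each list per library showed. Lens genes, which encode crystallins and other lens fibre proteins, summed to 17784 CPM in 6.0 months replicate 1, to 2247 CPM in 4.5 months replicate 1 and to 863 CPM in 1.5 months replicate 2. The other libraries held 12 to 72 CPM. Cornea and surface epithelium genes summed to 5651 CPM in 1.5 months replicate 1, where mural cell and fibroblast genes summed to 6949 CPM. Erythrocyte genes summed to 144 CPM in 4.5 months replicate 1. Cytosolic ribosomal protein genes stood at 18696 to 25609 CPM in 3.0 months replicate 2, 4.5 months replicates 2 and 3 and 6.0 months replicate 2, below the other libraries.

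**Figure D1:**
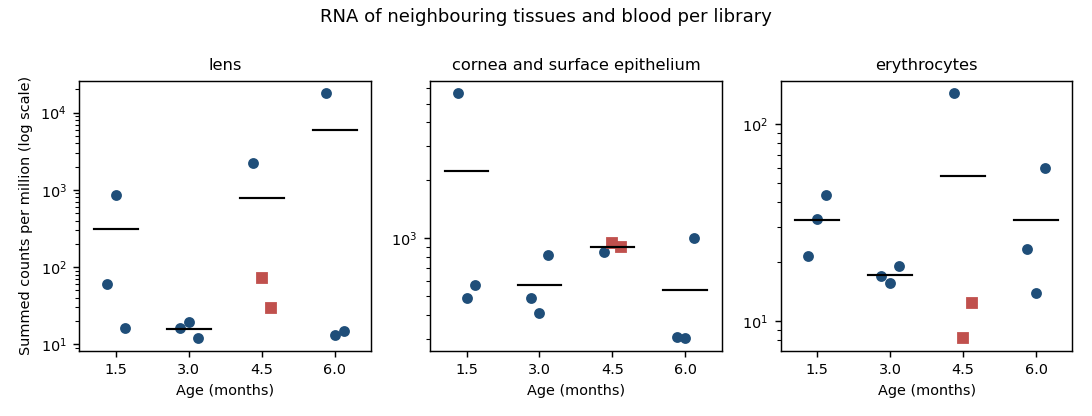
Summed CPM (log scale) of the lens, the cornea and surface epithelium, and the erythrocyte lists in each of the 12 libraries, grouped by age; each point is 1 library. Lens RNA reached 17784 CPM in 6.0 months replicate 1, and surface epithelium RNA 5651 CPM in 1.5 months replicate 1.

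Between 1.5 and 6.0 months, the genes past the threshold included rises of some immune cell genes and falls of some myelin and photoreceptor genes. The zinc transporter gene slc30a8 rose from 41.8 ± 16.2 to 399 ± 103 CPM (SD, n = 3; log2 change 3.25 ± 0.52, SE, adjusted p = 0.019, edgeR). The gene palmd rose from 2.43 to 23.1 CPM (3.25 ± 0.32, edgeR adjusted p = 0.00292). The leukocyte gene ptprc (CD45) rose by 1.95 ± 0.37, the macrophage mannose receptor gene mrc1b by 2.50, and csf1ra, a receptor for a macrophage growth factor, by 1.92. At 6.0 months replicate 2 was the highest for these 3 (mrc1b 67.39 CPM against 30.43 and 20.25, csf1ra 16.76 against 7.074 and 6.058), and for stat3 (348.9 against 220.8 and 155.2). Of the falls, tyrp1b, an enzyme of melanin synthesis, had log2 -3.41 ± 0.72 (42.7 ± 14.2 to 4.02 ± 2.28 CPM). The myelin genes mpz and plp1b had -3.30 ± 0.61 (80.6 ± 49.4 to 8.18 ± 2.11 CPM) and -2.53. The short-wavelength cone opsin gene opn1sw had log2 -1.77 ± 0.16 (761 ± 92.1 to 222 ± 10.6 CPM, edgeR adjusted p = 0.00101). Other genes of the rule were malrd1 (2.09), si:ch73-40a2.1 (1.97), abi3bpb (1.83), creg2 (1.80) and fbf1 (1.79) among the rises, and cd59 (-2.86), xpnpep2 (-1.89), fa2h (-1.66), pdyn (-1.59) and atoh7 (-1.58) among the falls.

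Of 21 tested microglia and macrophage genes, 6 rose between 1.5 and 6.0 months, among them csf1r (1.40), csf3r (1.76), ptprc and csf1ra, 15 did not pass, and 15 rose when adjusted over the list alone. Their median log2 change was 1.76 (camera adjusted p = 1.18e-14, 4.78e-12 without 6.0 months replicate 2, adjusted p = 0.313 with an estimated correlation). The neutrophil list was higher as well (1 of 8 genes rose, csf3r; 2 adjusted over the list alone; median 1.45; camera adjusted p = 0.000185, adjusted p = 0.559 with an estimated correlation). Among 21 interferon response genes irf8 (1.59) and parp9 (0.88) rose, 2 also when adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.676 with an estimated correlation). The antigen presentation list (1 of 20, erap1b; 9 up and 1 down adjusted over the list alone), the NF-kB list (2 of 26, nfkb2 at 1.64 and tnfrsf1a at 1.25) and the glial stress response list (2 of 21, cntf at 1.74 and stat3 at 0.96) also passed upward. Their camera adjusted p was 0.00126, 0.00421 and 0.028. For these 3 lists the adjusted p with an estimated correlation was 0.676, 0.559 and 0.676.

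Myelin and photoreceptor lists were lower at 6.0 than at 1.5 months. In the oligodendrocyte and myelin list 4 of 17 genes fell (mpz, plp1b, ugt8 at -1.5 and olig2 at -1.42; 8 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 4.82e-09, adjusted p = 0.559 with an estimated correlation). In the rod list 2 of 19 genes fell, rom1a (-1.23) and rom1 (-0.97), which encode disc rim proteins. Adjusted over the list alone 9 fell and 1 rose (median -0.63, camera adjusted p = 0.000375, adjusted p = 0.676 with an estimated correlation). In the cone list opn1sw2 (-0.79), a short-wavelength opsin, was the 1 of 18 genes that fell (6 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.313 with an estimated correlation). The outer segment list had 5 of 27 genes fall, among them prph2b (-0.81), rom1a and rom1 (6 adjusted over the list alone; camera adjusted p = 0.00667, adjusted p = 0.732 with an estimated correlation).

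The progenitor, cell cycle, ganglion cell and oxidative phosphorylation lists were also lower at 6.0 than at 1.5 months, with few or none of their genes past the threshold downward. Progenitor and ciliary margin genes had 4 of 32 fall, stmn1b (-1.48), fabp7 (-1.22), sox4 (-0.83) and the neurogenic factor gene atoh7 (6 adjusted over the list alone; camera adjusted p = 6.65e-05, adjusted p = 0.313 with an estimated correlation). Cell cycle genes had rrm2b and bub1 fall and cdc20b rise among 50 (camera adjusted p = 8.34e-05, adjusted p = 0.676 with an estimated correlation). Of 19 ganglion cell genes atoh7 fell (median -0.57; camera adjusted p = 0.000121, adjusted p = 0.676 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes lay below 0 in 80 of 84 cases (median -0.41, camera adjusted p = 1.16e-10, adjusted p = 0.676 with an estimated correlation), although the 1 gene past the threshold, ndufs1, rose by 0.92. Mueller glia (fabp7 fell; camera adjusted p = 0.00267) and glycolysis (hk2 rose; camera adjusted p = 0.00629) each had an adjusted p = 0.559 with an estimated correlation. Ribosomal proteins (camera adjusted p = 0.000185) and the proteasome (camera adjusted p = 0.0218) had no gene past the threshold and an adjusted p = 0.825 with an estimated correlation. Extracellular matrix, cholesterol synthesis and skeletal muscle genes (camera adjusted p = 0.00667, 0.00774 and 0.0151) had an adjusted p = 0.732 with an estimated correlation, and pigment cell genes (tyrp1b fell, camera adjusted p = 0.0183) had 0.749. Extracellular matrix RNA was at 9121 CPM in 1.5 months replicate 1, the library with surface epithelium RNA.

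The remaining lists did not pass between 1.5 and 6.0 months. Camera adjusted p values were 0.494 for RPE and visual cycle, 0.061 for lymphocytes, 0.968 for erythrocytes, 0.162 for lens (median 4.05), 0.273 for surface epithelium (evpl rose), 0.496 for endothelium (aplnra fell by 2.75), and 0.373 for mural cells. For retinal neurons they were 0.637 for bipolar cells (cabp5b fell), 0.191 for amacrine and 0.726 for horizontal cells. They were 0.652 for complement (cd59 fell), 0.538 for heat shock, 0.736 for endoplasmic reticulum stress, 0.218 for antioxidant enzymes (hmox1 and gsr rose), and 0.952 for DNA damage and senescence (rrm2b fell). Further values were 0.233 for synaptic genes (unc13b rose, syp fell), 0.403 for lysosome, 0.142 for the circadian clock (nr1d4a rose, ciart fell), 0.18 for immediate early genes, 0.899 for human macular degeneration genes and 0.184 for crystallin chaperones. Median and mean log2 change differed in sign for endothelium (0.03 and -0.07), horizontal cells (0.21 and -0.11), antioxidant enzymes (-0.16 and 0.22), endoplasmic reticulum stress (-0.06 and 0.03) and the macular degeneration genes (0.00 and -0.03). The test had the sign of the mean for endothelium and the macular degeneration genes and that of the median for the other 3. Of the genes always looked up, rpe65 (-0.58), gfap (-0.43), glula (-0.23), vim (0.48), mpeg1.1 (2.12), c3 (-0.76), cdkn1a (0.41) and pcna (-0.26) did not pass. The tested entries named rho and glulb averaged below 1 CPM at both ages, and c1qa and cfh matched no symbol. The rho entry is thus not the abundant rod opsin gene.

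In all, 575 genes passed between 1.5 and 6.0 months (edgeR, 363 higher and 212 lower), and 22 lists (6 higher, 16 lower, 0 with an estimated correlation, where 3 had an unadjusted p under 0.05). In each of the 575 the fish of both ages did not overlap; over all tested genes 30.61% did not overlap, where chance gives 10%. Leaving out replicates 1, 2 or 3 of 1.5 months gave 25, 48 and 8 genes, of 3.0 months 407, 716 and 376. For those of 4.5 months it was 1163, 359 and 325, and of 6.0 months 9, 70 and 275. Without the 3 libraries with lens RNA the count was 0. That fit also lacks a fish at 1.5 and a fish at 6.0 months, so the loss of lens RNA cannot be told apart from the loss of replicates. Of the 22 list calls 14 held in each of the 12 fits with 1 library left out. The others and their camera adjusted p were outer segment (0.136 without 1.5 months replicate 1), pigment cells (0.19 without 1.5 months replicate 3 and 0.271 without 6.0 months replicate 2), glial stress (0.117 and 0.0676 without 1.5 months replicates 2 and 3, 0.0814 without 6.0 months replicate 2) and skeletal muscle (0.349 without 6.0 months replicate 1). They were also ribosomal proteins (0.223 without 6.0 months replicate 2), proteasome (0.19 without 1.5 months replicate 3, 0.288 without 6.0 months replicate 2), extracellular matrix (0.484 without 1.5 months replicate 1, 0.0579 without 6.0 months replicate 1) and cholesterol synthesis (0.152 and 0.0592 without 1.5 months replicates 1 and 3, 0.175 without 6.0 months replicate 2).

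**Figure D2:**
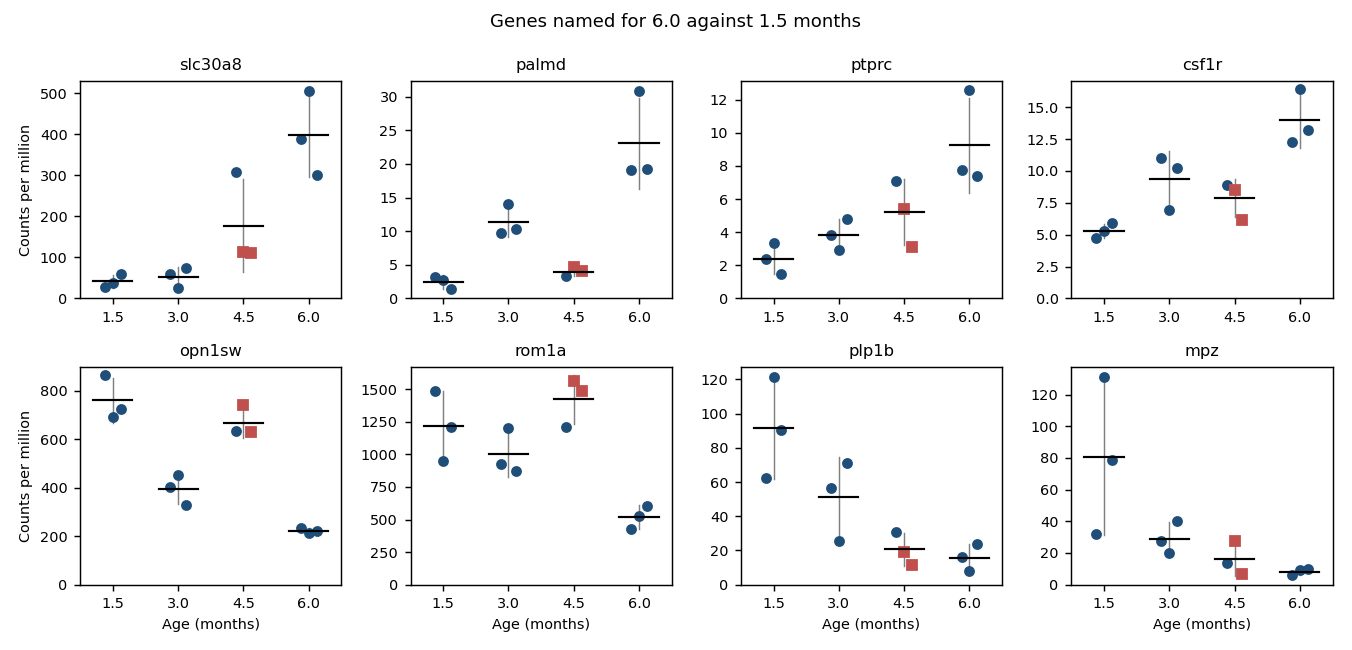
CPM of 8 genes against age in months; points are libraries (red squares: replicates 2 and 3 of 4.5 months), black bars mark the means and grey lines the SD of 3 fish. The mean of slc30a8 went from 41.8 CPM at 1.5 months to 399 CPM at 6.0 months, and that of plp1b from 91.4 to 15.8 CPM.

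The linear trend tested the slope of each gene against age in months, which a step at a single age can also produce. The cone list, which passed below, had mean centred log2 CPM of 0.0934, 0.0966, 0.122 and -0.312 at the 4 ages. A call in the trend therefore does not show a steady change. Among the named genes of the rule (mean of at least 5 CPM), the steepest rises per month were those of slc30a8 (0.76 ± 0.10, SE, log2 per month), mrc1b (0.54), si:ch73-40a2.1 (0.42), ptprc (0.42) and the cytokine signalling factor gene stat6 (0.38). The myelin genes mbpb, mpz and plp1b had slopes of -0.81, -0.72 and -0.59, beside tyrp1b (-0.76) and cd59 (-0.64). The heme oxygenase gene hmox1 also rose (edgeR adjusted p = 0.000594): it had 0 counts in the fish of 1.5 and of 3.0 months, where 3 counts over the group would be 0.0226 and 0.0254 CPM, and 1.06 CPM at 6.0 months. Of 21 microglia genes 6 rose (ptprc, lcp1, csf3r and itgb2 among them), and 16 rose adjusted over the list alone (camera adjusted p = 8.51e-16, adjusted p = 0.223 with an estimated correlation). Of 17 oligodendrocyte genes 5 fell (10 adjusted over the list alone; camera adjusted p = 1.44e-13, adjusted p = 0.223 with an estimated correlation). Of 32 progenitor genes stmn1b, atoh7 and fabp7 fell (7 adjusted over the list alone; camera adjusted p = 2.15e-05, adjusted p = 0.223 with an estimated correlation).

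Upward in the trend, interferon response (8.64e-07; parp9 and irf8 rose; 3 adjusted over the list alone), neutrophils (3.91e-05; csf3r rose), antigen presentation (0.000402), NF-kB (0.00112; nfkb2 and tnfrsf1a rose), lens (0.0183), glial stress (0.0435) and lymphocytes (0.0464) also passed by camera adjusted p. With an estimated correlation their adjusted p was 0.472, 0.289, 0.472, 0.289, 0.723, 0.658 and 0.638 in that order. Downward, oxidative phosphorylation (9.06e-11), ganglion cells (3.83e-07), cell cycle (8.64e-07; bub1 and nusap1 fell), ribosomal proteins (0.00017), Mueller glia (0.000514), skeletal muscle (0.00209), glycolysis (0.00271), extracellular matrix (0.00291), cones (0.00751), pigment cells (0.0101), cholesterol synthesis (0.0149), circadian clock (0.0296) and proteasome (0.0436) passed. For these the adjusted p with an estimated correlation was 0.652, 0.472, 0.472, 0.723, 0.289, 0.652, 0.34, 0.658, 0.361, 0.669, 0.669, 0.545 and 0.724. Rods did not pass the trend (camera adjusted p = 0.096), nor did the outer segment list (0.0987).

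**Figure D3:**
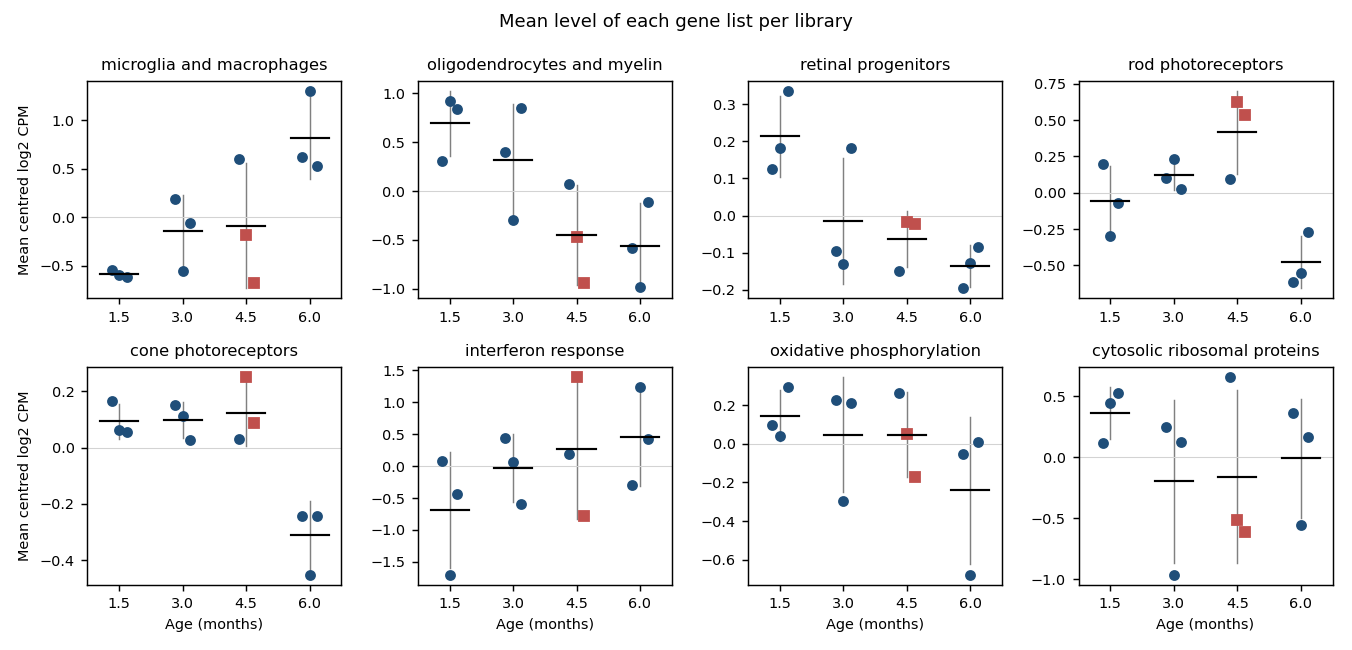
Mean centred log2 CPM of the members of 8 gene lists in each library (points; red squares: replicates 2 and 3 of 4.5 months) against age in months; black bars mark the means and grey lines the SD of 3 fish. The microglia list averaged -0.59 at 1.5 months and 0.82 at 6.0 months.

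The trend passed for 242 genes (edgeR, 149 higher and 93 lower), of which 130 and 83 also passed in the same direction between 1.5 and 6.0 months. It passed for 23 lists (8 higher, 15 lower, 0 with an estimated correlation, where 6 had an unadjusted p under 0.05). Without replicates 1, 2 or 3 of 1.5 months the trend gave 30, 27 and 15 genes, of 3.0 months 230, 350 and 126. Leaving out those of 4.5 months gave 251, 168 and 240, and of 6.0 months 29, 39 and 243. It gave 1 without the 3 libraries with lens RNA, a fit that also has fewer fish at 1.5, 4.5 and 6.0 months. In that fit the camera adjusted p was 0.055 for skeletal muscle, 0.233 for glial stress, 0.109 for lymphocytes and 0.103 for the circadian clock, so these calls ended. Without the Resub libraries (replicates 2 and 3 of 4.5 months, so marked in the labels) the proteasome call of the trend ended (0.0636). Of the 23 list calls 13 held in each of the 12 fits with 1 library left out. Single libraries ended the calls of cones, ribosomal proteins and cholesterol synthesis (0.0581, 0.058 and 0.381 without 6.0 months replicate 2), extracellular matrix (0.22 without 1.5 months replicate 1), lens (0.556 without 6.0 months replicate 1, in the opposite direction) and pigment cells (0.162 without 1.5 months replicate 3, 0.104 without 6.0 months replicate 2). The circadian clock call ended without 1.5 months replicate 1, 4.5 months replicate 1 or 6.0 months replicate 3 (0.0667, 0.0522 and 0.118). Glial stress (0.057 to 0.203 without 1.5 months replicate 2, 3.0 months replicates 1 and 2, 4.5 months replicate 1 and 6.0 months replicates 1 and 2) lost its call in 6 fits. Lymphocytes (0.0503 to 0.184 without 3.0 months replicates 1 and 2, 4.5 months replicate 1 and each library of 6.0 months) and proteasome (0.0571 to 0.502 without 1.5 months replicate 3, 3.0 months replicates 1 and 3, 4.5 months replicate 3 and 6.0 months replicates 2 and 3) lost theirs in 6 fits each.

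Any difference among the 4 ages was found for 458 genes (edgeR; 4753 at an unadjusted p under 0.05), with csgr19h18orf21, nr1d4a, cntd2 and opn1sw at its top, named after their values were seen. Of these, cntd2 rose to 4.82 CPM at 3.0 months and stayed at 7.08 and 6.89 CPM after it. The other 3 had no steady course: opn1sw averaged 761, 395, 669 and 222 CPM, the Rev-erb family gene nr1d4a 3.61, 4.93, 29.0 and 8.80 CPM, and csgr19h18orf21 14.8, 11, 80.3 and 23.9 CPM. Without replicates 1, 2 or 3 of 1.5 months the count was 49, 44 and 18, of 3.0 months 98, 567 and 150. For those of 4.5 months it was 2295, 9 and 7, and of 6.0 months 41, 272 and 220.

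From 1.5 to 3.0 months, 4 genes passed. The gene crebzf, which encodes a leucine zipper transcription factor, rose from 21.3 ± 1.66 to 43.6 ± 4.24 CPM (log2 1.04 ± 0.14, edgeR adjusted p = 0.0408). The other 3, named after their values were seen because the rule passed over them, were cntd2 (0.925 to 4.82 CPM, log2 2.38) and the unnamed loci LOC107393714 (62.7 to 131.1 CPM, 1.06) and LOC107388002 (14.9 to 35.5 CPM, 1.25). Ribosomal protein genes were lower at 3.0 months (80 of 81 below 0, median -0.49, camera adjusted p = 4.46e-11), with 3.0 months replicate 2 at 18696 CPM for the list. Progenitor (camera adjusted p = 0.00271), pigment cell (0.00436), skeletal muscle (0.0052), extracellular matrix (0.0154), ganglion cell (0.0205) and lens (0.00192, median -6.87) lists were lower too, while microglia (0.00271, median 0.61) and interferon response (0.0167) were higher. For each of the 9 lists the adjusted p was 0.958 with an estimated correlation, and no member of them passed over all genes; adjusted over the list alone, 1 microglia gene rose and 1 progenitor gene fell.

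No gene was lower at 3.0 than at 1.5 months by edgeR (0 past the threshold, 1040 lower at an unadjusted p under 0.05), while DESeq2 called 131 lower and voom 167. In both directions edgeR had 2605 genes at an unadjusted p under 0.05. Non-overlapping groups were seen in 21.45% of genes, against 10% by chance. Without replicates 1, 2 or 3 of 1.5 months the count was 1, 0 and 0, of 3.0 months 2, 0 and 1. Leaving out those of 4.5 months gave 157, 1 and 1, and of 6.0 months 1, 7 and 2. Of the 9 list calls 3 (ribosomal proteins, lens and progenitors) held in each fit with 1 library left out. Those of microglia and skeletal muscle (0.0536 each) and interferon response (0.203) ended without 3.0 months replicate 1, and those of pigment cells (0.478), ganglion cells (0.478) and extracellular matrix (0.235) without 3.0 months replicate 2. Leaving out libraries of 1.5 months ended the calls of extracellular matrix (0.879, replicate 1), interferon response and ganglion cells (0.455 and 0.162, replicate 2) and pigment cells (0.157, replicate 3).

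From 3.0 to 4.5 months, genes of the circadian clock moved apart. The Rev-erb family gene nr1d4a rose from 4.93 ± 1.72 to 29.0 ± 6.92 CPM (log2 2.55 ± 0.25, edgeR adjusted p = 0.00346). The period genes per3 and per2, which are core repressors of the clock, fell by 1.39 (224 to 85.5 CPM) and 1.04. Among 36 clock genes these 3 passed (1 up and 2 down; 3 up and 8 down adjusted over the list alone), and the list was lower (camera adjusted p = 0.0169, adjusted p = 0.956 with an estimated correlation). The stress-response gene ndrg1 rose from 118 ± 24.7 to 832 ± 546 CPM (2.82 ± 0.50), with 1161 and 1133 CPM in the Resub libraries and 202 CPM in 4.5 months replicate 1. Rises were also those of csgr19h18orf21 from 11 to 80.3 CPM (2.87), the dopamine receptor gene drd4b (1.25) and the netrin gene ntn4 (1.21). The bipolar cell gene cabp5a fell from 741 to 311 CPM (-1.25), as did adad2 (-1.98), si:ch1073-390k14.1 (-1.48) and trpa1 (-1.31).

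**Figure D4:**
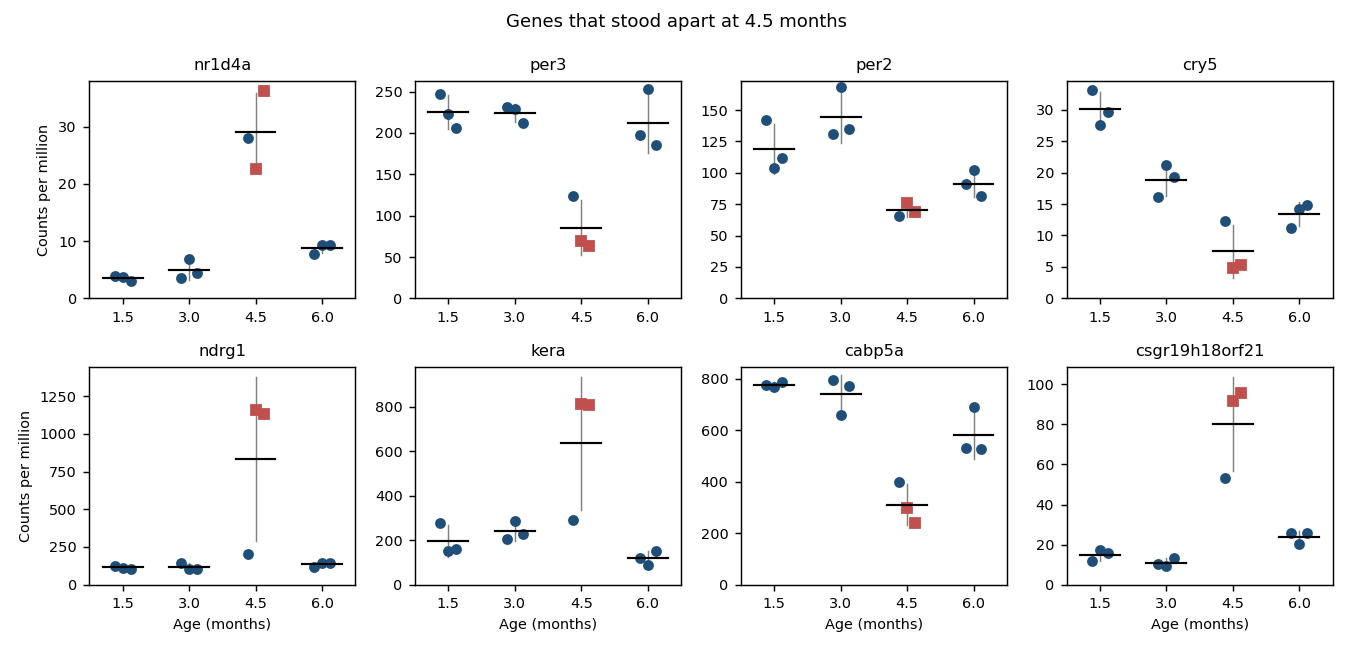
CPM of 8 genes against age in months; points are libraries (red squares: replicates 2 and 3 of 4.5 months), black bars mark the means and grey lines the SD of 3 fish. Mean nr1d4a was 29.0 CPM at 4.5 months against 3.61 to 8.80 CPM at the other ages, and mean per3 was 85.5 CPM against 212 to 225 CPM.

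Other lists passed between 3.0 and 4.5 months without a gene past the threshold in them. Ganglion cell genes lay below 0 in 19 of 19 cases (camera adjusted p = 9.23e-06; 1 fell adjusted over the list alone). The oligodendrocyte (4.51e-05; 1 fell adjusted over the list alone), synaptic (0.00814; 1 up and 4 down adjusted over the list alone) and cell cycle (0.00873) lists were lower. Lens (0.000528, median 7.33, with 2247 CPM in 4.5 months replicate 1), rods (0.00814, median 0.42) and lysosome (0.0169) were higher. For each of these 7 lists the adjusted p was 0.956 with an estimated correlation.

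In all, 66 genes passed (edgeR, 24 higher and 42 lower; 3052 at an unadjusted p under 0.05; 18.34% of genes with non-overlapping groups, 10% by chance). Without replicates 1, 2 or 3 of 1.5 months the count was 46, 36 and 24, of 3.0 months 2, 48 and 14. For those of 4.5 months it was 760, 2 and 3, and of 6.0 months 34, 140 and 39. It was 4 without the Resub libraries and 441 without the 3 libraries with lens RNA. Of the 8 list calls those of ganglion cells and oligodendrocytes held in each fit with 1 library left out. Without the Resub libraries ganglion cells had 0.486, oligodendrocytes 0.386 and the clock 0.486, and rods had 0.761 in the opposite direction, so 4 of the 8 calls ended. Leaving out 4.5 months replicate 1 ended the calls of cell cycle (0.264), lens (0.0542), lysosome (0.186) and synaptic genes (0.209). Those of the clock (0.0688) and rods (0.0862) ended without 4.5 months replicate 2. Without 3.0 months replicate 2 the clock had 0.129, lysosome 0.132 and synaptic genes 0.564, and without 3.0 months replicate 3 cell cycle had 0.155 and rods 0.0639.

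From 4.5 to 6.0 months, some photoreceptor genes fell and several genes returned towards their earlier levels. Of 19 rod genes 5 fell, among them rom1a (-1.45 ± 0.21; 1423 ± 187 to 521 ± 92.2 CPM), rom1 (-1.26), the recoverin gene rcvrna (-1.08) and pde6g (-0.98), a subunit of the rod phosphodiesterase. Adjusted over the list alone 14 fell (median -1.08, camera adjusted p = 1.7e-17, adjusted p = 0.178 with an estimated correlation). In the cone list 1 of 18 genes fell, opn1sw2 (-0.92; 4 adjusted over the list alone; camera adjusted p = 0.000133, adjusted p = 0.178 with an estimated correlation). In the outer segment list 5 of 27 fell, among them rom1a and prph2b (-1.01; 1 up and 9 down adjusted over the list alone; camera adjusted p = 6.88e-08, adjusted p = 0.61 with an estimated correlation). The amacrine neuropeptide gene vip fell by 0.93 and the photoreceptor synapse gene cabp4 by 0.79. The gene palmd rose by 2.54 (3.97 to 23.1 CPM) and per3 by 1.31, with myot (1.08), syt7 (1.03) and dedd2 (0.97). The falls of ndrg1 (-2.62), csgr19h18orf21 (-1.75) and nr1d4a (-1.72) came after their rises, and the corneal keratocyte gene kera (-2.42; 637 ± 299 to 119 ± 31.3 CPM) and si:ch73-366l1.5 (-1.78) fell. At 4.5 months kera stood at 811.5 and 807.2 CPM in the Resub libraries and 290.9 CPM in replicate 1, and si:ch73-366l1.5 at 108.3 CPM in each of the former and 61.07 CPM in the latter.

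Without a gene past the threshold, oxidative phosphorylation (camera adjusted p = 5.77e-09, adjusted p = 0.975 with an estimated correlation; 3 fell adjusted over the list alone), cholesterol synthesis (4.6e-05; 0.882; 4 fell) and proteasome (0.0444; 0.975; none) were lower at 6.0 than at 4.5 months. Microglia (2.81e-07; 4 rose adjusted over the list alone), glial stress (0.00273; 3 rose), immediate early genes (0.00358; 2 rose) and lymphocytes (0.0145) were higher, each with an adjusted p of 0.61 with an estimated correlation. So were ganglion cells (0.021) and antigen presentation (0.021; 1 rose), each with an adjusted p of 0.975 with an estimated correlation. Lens RNA stood at 17784 CPM in 6.0 months replicate 1.

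In all, 124 genes passed (edgeR, 36 higher and 88 lower; 3429 at an unadjusted p under 0.05; 21.06% of genes with non-overlapping groups, 10% by chance). Without replicates 1, 2 or 3 of 1.5 months the count was 58, 58 and 31, of 3.0 months 36, 302 and 39. Leaving out those of 4.5 months gave 1107, 3 and 1, and of 6.0 months 0, 39 and 44. It was 0 without the Resub libraries. Of the 12 list calls 8 held in each fit with 1 library left out. Leaving out the Resub libraries ended 8 of them: microglia had 0.531, glial stress 0.748, lymphocytes 0.706, antigen presentation 0.45, cholesterol synthesis 0.0644 and outer segment 0.309. The other 2, immediate early genes (0.784) and ganglion cells (0.45), were then in the opposite direction. Rods had 3.97e-05 and cones 0.0436 in that fit. The camera adjusted p of ganglion cells was 0.151, 0.244, 0.154 and 0.385 without 4.5 months replicates 2 and 3 and 6.0 months replicates 1 and 3. For lymphocytes it was 0.0579 and 0.0541 without 4.5 months replicates 2 and 3, for antigen presentation 0.191 without 4.5 months replicate 3 and 0.344 without 6.0 months replicate 2, and for the proteasome 0.627 without 4.5 months replicate 1 and 0.535 without 6.0 months replicate 2. No gene passed in both this step and the step from 1.5 to 3.0 months (0 shared, where independent lists would share 0.00695 higher and 0 lower).

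From 1.5 to 4.5 months, 8 clock genes, some myelin and synaptic genes and the ganglion cell gene stmn4 changed. Of 36 clock genes 8 passed (2 up and 6 down; 7 up and 15 down adjusted over the list alone). The rises were nr1d4a (3.00 ± 0.26, edgeR adjusted p = 0.000736) and aanat1 (1.42), an enzyme of melatonin synthesis, and the falls included cry5 (-2.02), per3 (-1.40), ciart (-1.14) and nr1d2b (-1.12). In 4.5 months replicate 1, cry5 (12.29 CPM) and ciart (17.66 CPM) lay within the range of the other ages, unlike in the Resub libraries (means of 5.039 and 12.8 CPM). In that replicate per3 (123.3 CPM) and nr1d2b (221.4 CPM) lay below the range of the other ages. The list was lower (camera adjusted p = 0.00386, adjusted p = 0.837 with an estimated correlation). Among the named genes of the rule (mean of at least 5 CPM), the germ-cell helicase gene ddx4 had the largest fall (-5.86 ± 1.13, 15.6 ± 1.06 to 0.267 ± 0.0451 CPM), and tyrp1b (-3.09), adad2 (-2.25) and plp1b (-2.15) fell too. Among the same genes the rises of ndrg1 (2.87), csgr19h18orf21 (2.43), malrd1 (2.38) and nr2f6 (1.88) were the next largest after nr1d4a. Of these nr2f6 stood at 180 and 168 CPM in the Resub libraries and at 49.8 CPM in 4.5 months replicate 1.

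Oligodendrocyte genes ugt8 (-1.61), olig2 (-1.61) and plp1b fell among 17 from 1.5 to 4.5 months (7 adjusted over the list alone; camera adjusted p = 1.69e-07). Of 19 ganglion cell genes stmn4 fell (-1.09; 10 adjusted over the list alone; 2.21e-09), and of 50 cell cycle genes tk1 (-1.41), bub1 (-1.18) and rrm2b (-0.53) fell (8 adjusted over the list alone; 0.00036). In the synaptic list slc17a6b (-1.43), homer1b (-0.87) and syn1 (-0.83) fell and cabp4 (0.67) rose among 56 (3 up and 10 down adjusted over the list alone; 0.0219). In the progenitor list stmn1b (-1.35), fabp7 (-1.01) and sox4 (-0.87) fell among 32 (0.00386). Mueller glia (fabp7 fell; 0.00386), pigment cells (tyrp1b fell; 0.0098), ribosomal proteins (6.22e-06), skeletal muscle (0.00036) and extracellular matrix (0.00223) were lower. Rods (grk1b rose by 1.28, with 619.8 and 575.1 CPM in the Resub libraries and 295 CPM in 4.5 months replicate 1; 0.00036), interferon response (irf8 by 1.26 and parp9 by 0.66; 0.000887), microglia (0.00386) and neutrophils (cxcr2 by 1.68; 0.0236) were higher. Erythrocyte genes had a median of 0.78 without a call (camera adjusted p = 0.828), with 144 CPM in 4.5 months replicate 1, and carried-over blood was not tested for this step. For each of these 14 lists the adjusted p was 0.837 with an estimated correlation. Among lists without a call, bipolar cells had cabp2 (0.66) and cabp2b (0.73) rise and cabp5a (-1.32) and cabp5b (-0.87) fall. Horizontal cells had lhx1 (0.74) and the connexin gene gja10 (1.34) rise, amacrine cells had gad1 (0.62) and vip (0.62) rise, and kera (1.70) rose.

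In all, 627 genes passed (edgeR, 229 higher and 398 lower; 4605 at an unadjusted p under 0.05; 26.4% of genes with non-overlapping groups, 10% by chance) and 15 lists. Without replicates 1, 2 or 3 of 1.5 months the count was 179, 12 and 28, of 3.0 months 457, 941 and 369. For those of 4.5 months it was 2725, 7 and 20, and of 6.0 months 342, 769 and 359. It was 1 without the Resub libraries. Of the 15 list calls 7 held in each fit with 1 library left out. Without the Resub libraries 7 of the 15 ended: the clock had 0.151, rods 0.43, Mueller glia 0.602, and skeletal muscle, extracellular matrix and pigment cells 0.805 each, while ribosomal proteins passed in the opposite direction (0.0057). Ganglion cells had 0.00604 and oligodendrocytes 0.012 in that fit. Leaving out 4.5 months replicate 1 ended the calls of cell cycle (0.0735), microglia (0.363), neutrophils (0.693), progenitors (0.0862) and synaptic genes (0.363). Interferon response (0.141) and pigment cells (0.0609) lost theirs without 4.5 months replicate 2. Without 1.5 months replicate 1 extracellular matrix had 0.168, without replicate 2 neutrophils 0.0612 and synaptic genes 0.091, and without replicate 3 pigment cells 0.161.

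From 3.0 to 6.0 months, photoreceptor and myelin lists were lower and immune lists higher, though no single gene passed. Rods had a median log2 change of -0.65 with 18 of 19 below 0 (6 fell adjusted over the list alone; camera adjusted p = 1.15e-12, adjusted p = 0.345 with an estimated correlation). Cones (-0.27; 4; 1.94e-06, adjusted p = 0.111 with an estimated correlation) and outer segment (-0.36; 2; 1.34e-06; 0.391) were lower too. Oligodendrocytes had a median of -0.94 (5 fell adjusted over the list alone; camera adjusted p = 1.85e-09), and microglia of 0.95 (9 rose adjusted over the list alone; 5.89e-13), both with an adjusted p of 0.345 with an estimated correlation. Oxidative phosphorylation (5.89e-13, adjusted p = 0.469 with an estimated correlation), cholesterol synthesis (4.81e-07; 0.374), cell cycle (0.000132; 0.543), ganglion cells (0.013; 0.707) and Mueller glia (0.026; 0.469) were lower. NF-kB (0.000154), glial stress (0.000173), lysosome (0.000758) and lymphocytes (0.00172) were higher with an adjusted p of 0.345 with an estimated correlation. In the same form immediate early genes (0.000891; 4 rose adjusted over the list alone) had 0.369, neutrophils (0.000891) 0.374, antigen presentation (0.000489) 0.446 and interferon response (0.00206) 0.689, all higher. Lens (1.34e-06, median 10.83, with 17784 CPM in 6.0 months replicate 1) and crystallin chaperones (0.0168) had 0.469, and ribosomal proteins (0.032, higher) 0.887.

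By edgeR 0 genes passed between 3.0 and 6.0 months (1730 at an unadjusted p under 0.05, smallest adjusted p 0.06244), while DESeq2 called 206 and voom 23; 13.58% of genes had non-overlapping groups, against 10% by chance. The edgeR count was 1 without 1.5 months replicate 3 and 0 without any other single library. Of the 21 list calls 14 held in each fit with 1 library left out. Leaving out 3.0 months replicate 2 ended those of lymphocytes (0.0589) and crystallin chaperones (0.223) and turned ribosomal proteins downward (0.0125). The lens and epithelium covariates also turned ribosomal proteins downward past the threshold (0.0266). They ended the calls of cell cycle (0.383), lens (0.489) and crystallin chaperones (0.561). In 5 of 19 alternatives ribosomal proteins had the opposite direction. Leaving out 6.0 months replicate 1 ended those of lens (0.05), crystallin chaperones (0.138) and ribosomal proteins (0.757, in the opposite direction). Mueller glia had 0.23 without 3.0 months replicate 1 and 0.0988 without 6.0 months replicate 3, ribosomal proteins 0.43 without 6.0 months replicate 3, interferon response 0.118 without 3.0 months replicate 3 and 0.454 without 6.0 months replicate 2, and ganglion cells 0.542 and 0.982 without these libraries.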

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

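The alternatives that left out the 3 libraries with lens RNA, added lens and epithelium covariates or added a ribosomal covariate were chosen after the data were seen. Counts of genes within 1.5 times the reported ones were obtained with RLE size factors, with no filter on low counts (24371 genes tested) and with at least 10 counts in 6 libraries (19887 genes tested), except from 3.0 to 4.5 months, where RLE size factors gave 100 and the stricter filter 104 instead of 66 genes. In the order any difference, trend, 6.0 against 1.5, 3.0 against 1.5, 4.5 against 3.0, 6.0 against 4.5, 4.5 against 1.5 and 6.0 against 3.0 months, DESeq2 called 3189, 1140, 1921, 466, 928, 1222, 2112 and 206 genes, and limma voom with quality weights 7672, 1728, 2722, 508, 3635, 4270, 7188 and 23, against 458, 242, 575, 4, 66, 124, 627 and 0 by edgeR. Without the 2 Resub libraries, any difference gave 50 genes, 3.0 against 1.5 months 1, 4.5 against 3.0 months 4, 6.0 against 4.5 months 0 and 4.5 against 1.5 months 1; this leaves 1 library at 4.5 months, assumed to vary like the other groups. With the replicate number as a block (replicate block), any difference gave 214 genes, the trend 141, 6.0 against 1.5 months 495, 3.0 against 1.5 months 10 and 6.0 against 4.5 months 47. The residuals showed no clear pairing by number: 18 pairs of libraries with the same number correlated at r from -0.315 to 0.302 (mean 0.0536, 8 above 0.1), and 36 other pairs had a mean r of -0.0273. The replicate block ended 3 of 110 list calls, those of lens (0.132) and lymphocytes (0.0581) in the trend and of skeletal muscle for 6.0 against 1.5 months (0.0521). Without the 3 libraries with lens RNA, the trend gave 1 gene, 6.0 against 1.5 months 0, 3.0 against 1.5 months 0, 4.5 against 3.0 months 441, 6.0 against 4.5 months 199 and 4.5 against 1.5 months 1036. This setting also lowers the number of fish at 1.5, 4.5 and 6.0 months. With lens and epithelium covariates the counts were 77 for any difference, 139 for the trend, 212 for 6.0 against 1.5 months, 0 for 3.0 against 1.5 months, 26 for 4.5 against 3.0 months, 63 for 6.0 against 4.5 months and 305 for 4.5 against 1.5 months. With the ribosomal covariate they were 2303, 493, 1554, 32, 946, 1275, 1424 and 57 in the order above. With only the 2 ages compared, 3.0 against 1.5, 4.5 against 3.0 and 6.0 against 4.5 months gave 0 genes each, 4.5 against 1.5 months 104 and 6.0 against 1.5 months 609. The test against a fold of 1.5 gave 7 genes for 6.0 against 1.5 months, 1 for 3.0 against 1.5, 4 for 4.5 against 3.0, 0 for 6.0 against 4.5 and 6 for 4.5 against 1.5 months, which its construction explains, as it asks for a larger change. Leaving out 1 library at a time gave 7 to 2295 genes for any difference, 15 to 350 for the trend, 8 to 1163 for 6.0 against 1.5, 0 to 157 for 3.0 against 1.5, 2 to 760 for 4.5 against 3.0, 0 to 1107 for 6.0 against 4.5, 7 to 2725 for 4.5 against 1.5 and 0 to 1 for 6.0 against 3.0 months. The values for each library stand in the report, and the highest came without 4.5 months replicate 1 in 6 of these. That fit leaves only the Resub libraries at 4.5 months, the pair with the highest correlation (Spearman 0.9939). Leaving out the libraries with lens RNA does so too, so in both the spread at 4.5 months is that of this pair. Lists past the threshold were 18 to 27 for the trend, 19 to 24 for 6.0 against 1.5, 7 to 14 for 3.0 against 1.5, 7 to 16 for 4.5 against 3.0, 10 to 20 for 6.0 against 4.5, 13 to 17 for 4.5 against 1.5 and 19 to 26 for 6.0 against 3.0 months with 1 library left out. Of the 110 list calls, 0 ended with RLE size factors, 1 with no filter on low counts (lymphocytes in the trend, 0.0653), 20 without the Resub libraries, 20 without the libraries with lens RNA, 18 with the lens and epithelium covariates and 18 with the ribosomal covariate. Besides those in the report, lists in the opposite direction were lens in the trend (0.767 without the libraries with lens RNA, 0.853 with the lens and epithelium covariates), ganglion cells for 3.0 against 1.5 months (0.77 with the ribosomal covariate) and ribosomal proteins for 6.0 against 3.0 months (0.805 without the libraries with lens RNA, 0.913 with the ribosomal covariate). With an estimated correlation 0 lists passed in each of the 7 comparisons. The ribosomal covariate gave 5 lists for 3.0 against 1.5 months, leaving out the Resub libraries 20 for 4.5 against 3.0 months, and leaving out the libraries with lens RNA 24 for 6.0 against 4.5 months. Genes shared by the first and last step numbered 58 by DESeq2, 100 by voom, 1 with no filter, and 0 to 9 with 1 library left out, against 0 by edgeR. The separation of the ages had an exact permutation p of 0.03851 over all tested genes, and of 0.1571 to 0.4897 in the other forms. Except where its construction shows it, the cause was not tested for any of the values that moved. A reversal was counted only where a named gene was past the threshold in the reported fit or in the alternative, and 0 were found. Changes of direction in named genes past it in neither were not counted. Most calls of the named genes ended under at least 1 alternative, the test against a fold of 1.5 included. These were 54 of 54 calls for 6.0 against 1.5 months, 1 of 1 for 3.0 against 1.5 and 11 of 11 for 4.5 against 3.0 months. For 6.0 against 4.5 months they were 19 of 19, for 4.5 against 1.5 months 46 of 47 and for the trend 25 of 26. The exceptions were nr1d4a between 1.5 and 4.5 months and hmox1 in the trend, past the threshold under each alternative run for them.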

Other observations

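Some genes moved outside the lists or in lists without a call, and the genes of this paragraph were chosen after their values were seen. The ependymin gene epd fell from 7.76 CPM at 1.5 months to 0.329 CPM at 6.0 months (log2 -4.56, edgeR adjusted p = 0.00793), and prr18 fell from 24.6 to 10.8 CPM (-1.19). The gene clul1 averaged 618 CPM at 6.0 months and fell by 0.91 from 1.5 months. The apelin receptor gene aplnra of endothelium fell in the trend (-0.59 per month), as did the stress-response gene gadd45gb.1 (-0.36). From 1.5 to 4.5 months the glycolytic regulator gene pfkfb3 (0.96), the glutathione synthesis gene gclc (0.56), the chaperone gene fkbp4 (0.48) and psmd11b of the proteasome (0.41) rose, and the neuronal enolase gene eno2 fell (-0.84). The unnamed locus LOC107391139 had the highest mean CPM over the 12 libraries, with 2.22% to 3.087% of the counts at 1.5 months and 0.9564% to 1.438% at 6.0 months. Its rank within each library was not computed.

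The clock list held genes with opposite phases. Both Resub libraries lay above the range of the other 10 libraries for 6 of its 36 members and below it for 15, or 58.3% of the list against 16.2% of all tested genes. Of these 21 members, the third library of 4.5 months lay within the range of the 9 libraries of the other ages for 17 and outside it for 4. The gene clock was at 203.9 CPM in the Resub libraries on average, 105.2 CPM in the third library and 79.14 to 173 CPM at the other ages, and nr1d2a at 26.74, 200 and 77.91 to 215.7 CPM. Unlike these, nr1d4a was at 29.43 CPM in the Resub libraries and 28.1 CPM in the third, against 3.067 to 9.375 CPM.

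The tests below were chosen after the result was seen, except those of the order of the libraries for the microglia list and of the library batch at 4.5 months.

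The microglia and macrophage list rose with age, by a median log2 change of 1.76 between 1.5 and 6.0 months (camera adjusted p = 1.18e-14, but adjusted p = 0.313 with an estimated correlation). Carried-over red blood cells are argued against by the erythrocyte genes, whose upper quartile was 0.448, below the lower quartile of the microglia genes (1.43). That list had 8 tested genes and no haemoglobin gene, so it traces blood weakly, and it does not measure white blood cells. A library structure marked by ribosomal protein level is argued against as the whole cause, since the median was 1.88 with that covariate. A chance order of the libraries stays open. The list's level correlated with age at Pearson r = 0.77 (exact permutation p = 0.00413 over 369600 assignments, adjusted p = 0.0604 over 43 lists). Leaving out each pair of the libraries of 1.5 and 6.0 months in turn gave r = 0.647 to 0.737. Spearman rho was 0.691 (exact permutation p = 0.0178, adjusted p = 0.192). More immune cells, or more RNA per cell, with age may be the source and was not tested.

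Between 1.5 and 4.5 months 627 genes passed. A library structure marked by ribosomal protein level is argued against as the whole cause, as 96.3% of the calls were past the threshold with that covariate. A library batch shared by the 2 Resub libraries stays open. The third library of 4.5 months, of the same age without that mark, kept a median 30.9% of their difference from 1.5 months. Libraries of 3.0 and 6.0 months kept 29.3% to 47.6%, so the third library shared no more of the difference than other ages did. As it is a single library, a batch cannot be told apart from variation between fish of this age. Collection of the fish of 4.5 months at another time of day stays open for the clock genes. Of the 21 members outside the other libraries in both Resub libraries, 17 were within the range of the other ages in the third. These members were picked for Resub levels beyond those of the third library too, so this share cannot decide the question. The time of day of the 2 Resub fish and their library batch cannot be told apart. An earlier criterion, the share of the list past the threshold, restated the calls and was dropped; collection times are not given in the sources used here, and age was not tested apart from them.

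Rod and cone lists were lower at 6.0 months than at the other ages. Chance stays open: the exact permutation p of 6.0 months against the other libraries was 0.00909 for rods and 0.00455, the smallest possible, for cones, and the adjusted p was 0.313 for both over 172 tests of the lists at each age. A list at the smallest possible p cannot by itself reach an adjusted p under 0.05 over 172 tests, so the adjusted p could hardly decide this. Dilution by RNA from outside the retina is argued against as the whole cause, as the lower quartile of the bipolar, amacrine and horizontal genes was -0.195 and the upper quartile of the rod and cone genes -0.31 (medians -0.0406 and -0.506); an earlier criterion, no overlap between libraries in the difference of these means, was not met (-0.0322). A library structure marked by ribosomal protein level is argued against as the whole cause, as the median of the rods between 3.0 and 6.0 months was -0.577 with that covariate and -0.649 without it. Fewer or smaller photoreceptors at 6.0 months may also be the source, which was not tested.

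Other splits of the libraries into groups of the same sizes were counted, the real one included. For any difference 1 of 100 splits gave as many genes (real 458, highest other 215) and for the trend 1 of 100 (242, highest other 59). Only the real split reached these counts, which is the smallest share that 100 splits can give. The splits do not tell age apart from other structure that the real groups hold, such as the Resub libraries at 4.5 months. For the lists of the trend 11 of 100 splits gave as many (23, highest other 30), so chance cannot be excluded. Each comparison of 2 ages has 10 splits, too few for a share under 0.05. Genes, as splits with as many, real count and highest other, were 1, 575 and 0 for 6.0 against 1.5 months, 1, 4 and 0 for 3.0 against 1.5, 2, 66 and 1583 for 4.5 against 3.0, 1, 124 and 2 for 6.0 against 4.5, 1, 627 and 1 for 4.5 against 1.5, and 10, 0 and 0 for 6.0 against 3.0 months. Lists, in the same form, were 1, 22 and 21, 9, 9 and 21, 10, 8 and 23, 10, 12 and 30, 9, 15 and 29, and 3, 21 and 23. The median of the other splits was 18, 16, 17, 16, 19 and 17 lists in that order, and 17 for the trend. The real counts lay below it for 3.0 against 1.5, 4.5 against 3.0, 6.0 against 4.5 and 4.5 against 1.5 months. Many lists thus passed by camera with the preset correlation under other groupings too, so its adjusted p alone does not tie a list to age. The 1583 genes came from the split that put 3.0 months replicate 2 with 4.5 months replicates 2 and 3, which points to a structure of the samples; these libraries were low in ribosomal protein RNA (18696 to 25609 CPM).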
